A study of Zea mays with 6 samples.

How the data were processed

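Gene expression was measured by RNA sequencing in the sheath of leaf 2 of maize seedlings at the stage of 3 leaves. There were 6 libraries, 3 from wild-type plants (WT) and 3 from plants in which the long noncoding RNA GARR2 had been knocked out (GARR2KO). The replicates were biological replicates per the labels, the reads were 150 bp paired-end on an Illumina HiSeq, and the seedlings had received no treatment. The labels do not say how the knockout was made, whether the WT plants were its siblings, or on which days the plants were grown.

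The deposited values were taken as FPKM, fragments per kilobase of gene and scaled to the size of the library, because Cufflinks and Cuffdiff are named in the submitters' processing notes and the files have no header that names a unit. RPKM values would look the same. TopHat2 and the genome build B73 RefGen_v4 are named in the same notes, without versions, and the annotation release and any filter are not given in the sources used here. The authors deposited 1 table per library, not pooled, with 44146 gene identifiers and 1 value each. Sums of FPKM ran from 618107 to 675513 per library.

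The gene table at hand belongs to another assembly, Zm-B73-REFERENCE-NAM-5.0, and 0 of the 44146 identifiers matched any entry in it. Genes therefore carry identifiers only, no coordinates are given, and the 34 gene lists fixed before the data were examined (hormone pathways, cell wall, photosynthesis, defence, cell cycle and tissue markers among them) had no matched member and were not tested. GARR2 itself could not be tied to an identifier and is not analysed here, so the genotype labels have no check on the targeted transcript.

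Depth was recovered from the values. Within a gene, low FPKM values were whole multiples of a step, and the most common ratio between libraries was shared by 346 to 420 genes of under 0.5 FPKM. With these ratios, all 6 values of a gene were whole multiples of 1 step, within 0.002 of a whole number, for 31076 of the 31076 genes above 0 (100.0%). A gene above 0 in 1 library passes this by construction, and genes above 0 in few libraries pass easily, so the share is no test for them. The step also gave whole gene lengths, within 0.02 bp, for 99.2% of genes with over 30 reads, against 49.7% when the step was doubled. Recovered reads per library over the listed genes numbered 20722307, 18314264 and 17750725 in WT replicates 1 to 3 and 19182497, 17723726 and 18489796 in GARR2KO replicates 1 to 3. The recovery was tested on simulated data of 6000 genes, where 99.2% of genes seen in at least 3 libraries came back exactly. Whether the counted unit was a read or a read pair is not given in the sources used here, and "reads" is used for both. At these depths 1 read in a gene of 2 kb was worth 0.024 to 0.0283 FPKM. Intervals and floors from reads cover counting error only. A floor is 3 reads over the 3 libraries of a genotype, and intervals are exact (Clopper-Pearson) at 95%. A fold against a floor takes the reads of the other genotype as counted, without their own counting error.

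The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1) with genotype as the only term, over 21531 genes with a mean of at least 1 FPKM over the 6 libraries. Calls had a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. In data simulated from the recovered reads for GARR2KO against WT, with 200 seeded genes, this test recovered 26.5% of changes of 1.25-fold, 70% of 1.5-fold, 88% of 2-fold and 100% of 4-fold over 21399 genes. It called 9 unchanged genes there. When nothing was changed, limma-trend called 0 of 21404 genes, with 1119 (5.2%) at an unadjusted p under 0.05, and voom called 0 of 21531, with 1079 (5%). The simulated reads were scaled by their own summed reads. The deposited FPKM are scaled by the recovered totals instead, whose ratio to the summed reads differs between the genotypes. The simulation does not cover that difference, which enters the main test. With only 200 changed genes its adjusted threshold was also stricter than in the data, where 9517 genes passed. Genes of similar level shared 1 dispersion. The recovered shares therefore do not give the recovery of the main test.

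The named genes follow a rule set before the data were examined. Since no identifier had a name, at most 2 that rose and 2 that fell are given, those with the largest fold change past the threshold whose values did not overlap between genotypes. A gene was counted as listed in a single genotype when it was at 0 in all 3 libraries of the other and at least 1 FPKM in all 3 of its own. At that minimum of 1 FPKM, 10 genes in WT and 7 in GARR2KO were at 0 in 1 library while the other 2 libraries of the genotype were at or above it; at 5 FPKM there were 0 in each. Chromosome order was not used here, so changed genes were scanned along the number in the identifier instead, a choice made after the data were seen. The largest number of genes changed 2-fold or more in any window of 100 tested genes was set against 10000 shuffles. Runs were windows above the 95th percentile of the shuffled maxima, trimmed to their outer changed genes, and were found without the genes listed in a single genotype. The scan was tested on 40 simulated sets, where it called 2.5% of random placements and 100% of planted segments of 300 genes.

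Alternatives set beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust moderation, a 2-fold minimum and leaving out each library. Added later were voom (limma) on the recovered reads, scaling of each library by its summed gene reads, removal of a spline trend on gene length and level, windows of 50 genes, and leaving out the runs. The same replicate numbers did not pair the libraries. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and exact tests used scipy 1.17.1.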

Results

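The transcriptome of the leaf sheath was compared between wild-type maize (WT) and GARR2 knockout plants (GARR2KO), with 3 libraries each. The sheath is the lower part of a grass leaf that wraps around the shoot. The comparison asks which transcripts differ in the sheath of untreated seedlings when the long noncoding RNA GARR2 is knocked out. Each library listed 44146 genes, of which 27763 to 28033 were above 0 in WT and 28013 to 28167 in GARR2KO. Recovered reads over these genes numbered 17750725 to 20722307 per WT library and 17723726 to 19182497 per GARR2KO library.

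The 6 libraries separated by genotype. The first principal component of log2(FPKM + 1) held 81.9% of the variance, with the WT libraries between -37.35 and -35.09 and the GARR2KO libraries between 34.38 and 37.39. The second component held 5.7% and set WT replicate 2, at -17.83, apart from the other WT libraries, at 6.94 and 11.49. Pearson's r across genes was 0.9960 to 0.9969 for the 6 pairs within a genotype and 0.9811 to 0.9836 for the 9 pairs between genotypes. Genes are not independent replicates, so r describes these libraries only. The chi-square of recovered reads per degree of freedom, which treats reads as independent molecules, was 2.43 to 4.99 within a genotype and 34.46 to 39.31 between genotypes. No 2 libraries thus held identical values. Whether reads or read pairs were counted is not known, so these values cannot tell whether 2 libraries came from the same RNA.

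In GARR2KO sheaths 4322 genes rose and 5195 fell, out of 21531 tested (limma-trend, Benjamini-Hochberg adjusted p under 0.05, n = 3 per genotype). These 9517 genes were 44.2% of those tested. Most of the changes were small. Of the changed genes, 6767 (71.1%) moved by less than 1.5-fold, with 3114 up and 3653 down. A further 1886 moved by 1.5- to 2-fold, with 776 up and 1110 down. Of the 864 genes that changed 2-fold or more, 432 rose and 432 fell. Both the count and the split depend on the processing: 640 rose and 690 fell with a pseudocount of 0.1, 459 and 398 with scaling by summed gene reads and 733 and 644 with voom, and 521 genes in all passed with a minimum mean of 5 FPKM. Among the 864, 93 rose and 94 fell by 4-fold or more. The 3 values of a genotype all lay above the 3 of the other for 9402 of the 9517 changed genes and for 56.2% of all tested genes, where chance gives 10%. The median log2 fold change of all tested genes was -0.01. Which direction was more frequent depended on the scaling: genes that rose were 45.4% of the calls on the deposited values, 47.3% after median-of-ratios scaling, 50.4% after quantile normalization, 54.3% when each library was scaled by its summed gene reads and 55.3% with voom on the recovered reads. The median log2 fold change was 0.04 under both of the last.

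**Figure D1:**
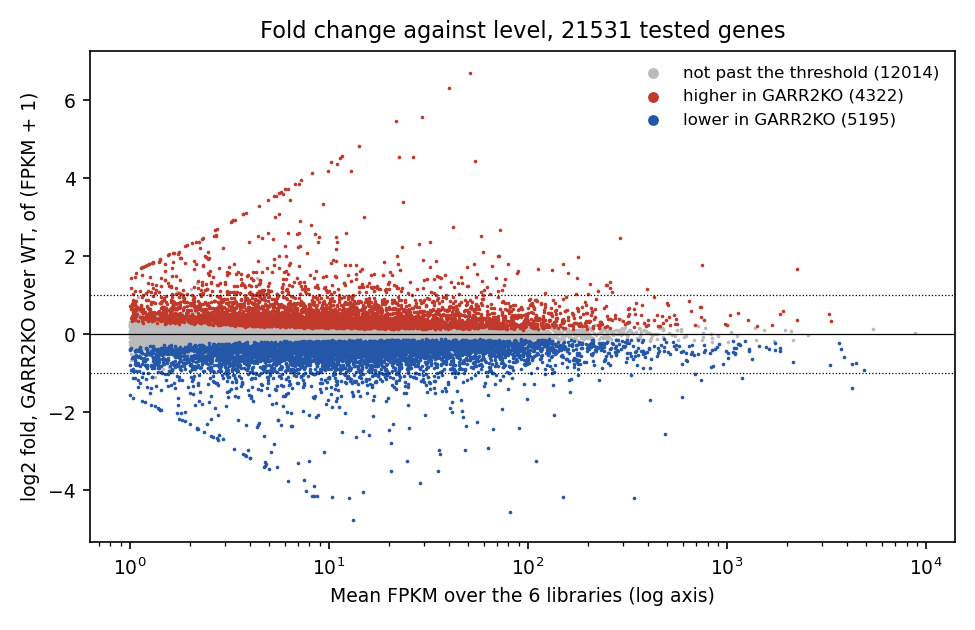
Log2 fold change of GARR2KO over WT, of FPKM + 1, against the mean FPKM over the 6 libraries on a log axis, 1 point per tested gene, with dotted lines at 2-fold. Red points are the 4322 genes that rose and blue points the 5195 that fell at an adjusted p under 0.05 (limma-trend); most lie inside the dotted lines.

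The 2 largest rises and the 2 largest falls on the log2(FPKM + 1) scale, among genes past the threshold whose values did not overlap between genotypes, follow. Zm00001d001134 was listed at 0 in the 3 WT libraries and rose to 102 ± 6.3 FPKM (SD, n = 3) in GARR2KO, with a log2 fold of 6.69 (SE 0.063, adjusted p = 7.12e-10, limma). It had 0 WT reads against 1379 GARR2KO reads, at least 455-fold higher against a floor of 3 reads. Zm00001d019414 rose from 0.029 ± 0.051 to 80.5 ± 6.3 FPKM, a log2 fold of 6.31 (SE 0.076, adjusted p = 1.75e-09, limma). It had 2 WT reads and 5984 GARR2KO reads, a ratio of 2960 with a counting interval of 820 to 24500. Zm00001d002480 fell from 26.6 ± 3.5 to 0.015 ± 0.026 FPKM, a log2 fold of -4.76 (SE 0.098, adjusted p = 2.65e-08, limma). It had 1779 WT reads and 1 GARR2KO read, a ratio of 1800 with a counting interval of 322 to 71000. Zm00001d052122 fell from 157 ± 17 to 5.88 ± 1.6 FPKM, a log2 fold of -4.54 (SE 0.163, adjusted p = 4.01e-07, limma). It had 2634 WT reads and 99 GARR2KO reads, a ratio of 26.9 with a counting interval of 22.0 to 33.2. By reads other genes fell further: the 33 genes listed only in WT had a median bound of 70.0-fold, reaching 986-fold. What these genes encode is not reported here, because the files do not pair identifiers with names.

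**Figure D2:**
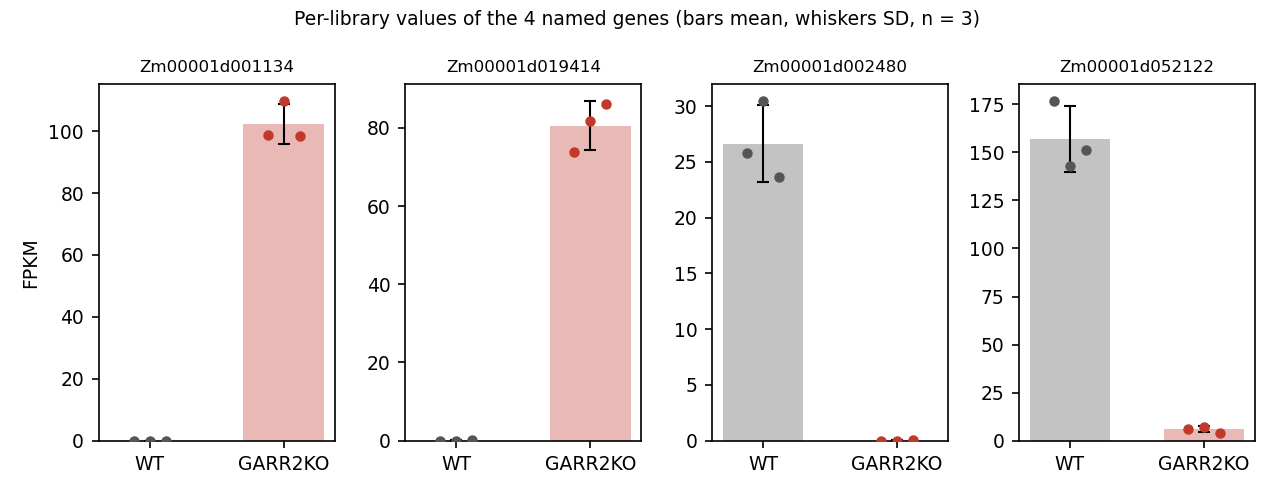
FPKM of the 4 genes in each library, with points for libraries, bars for the mean and whiskers for the SD (n = 3), each panel on its own linear axis from 0. Zm00001d001134 and Zm00001d019414 were higher in GARR2KO, at means of 102 and 80.5 FPKM, and Zm00001d002480 and Zm00001d052122 were higher in WT, at 26.6 and 157 FPKM.

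A set of 92 genes was listed at 0 in every library of one genotype and at 1 FPKM or more in every library of the other. Of these, 59 were listed only in GARR2KO and 33 only in WT. The other 9 splits of the 6 libraries gave at most 1 such gene, but each of them mixes the genotypes, so this is not a chance level. The 59 genes listed only in GARR2KO had a median of 2.85 FPKM there, reaching 102.3, and 12 of them were at 10 FPKM or more. Against the floor of 3 reads, and with their own reads taken as counted, they were at least 4.95-fold higher in GARR2KO. The median bound was 40.3-fold. The fewest reads of any of them was 15, so counting error in GARR2KO would lower the smallest bounds. The 33 genes listed only in WT had a median of 4.4 FPKM there, reaching 16.9, and 5 were at 10 FPKM or more. On the same terms they were at least 16.5-fold lower in GARR2KO, with a median bound of 70.0-fold. A level of 0 allows up to 3 reads in the genotype, so expression below that was not detectable at this depth.

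Genes past the threshold were more frequent among abundant transcripts. A change is easier to detect with more reads, and log2(FPKM + 1) compresses low values. Recovery by level was not simulated, so the order may reflect detection alone. Of 5787 genes at 1 to 4 FPKM, 32.7% changed, against 43.1% of 8814 genes at 4 to 16 FPKM, 52.2% of 5218 at 16 to 64, 63.5% of 1417 at 64 to 256 and 68.8% of 295 at 256 or more. The share that changed 2-fold or more did not follow this order. It was 4.8%, 3.8%, 3.5%, 3.6% and 5.4% from the lowest class to the highest, and 10.6%, 5.1%, 3.9%, 3.7% and 5.4% with a pseudocount of 0.1. With voom on the recovered reads it was 11.6%, 5.1%, 3.7%, 3.4% and 5.1%. Of the 295 most abundant genes, 68 rose and 135 fell, and their median log2 fold was -0.11. Falls outnumbered rises in this class, by less, and the median was nearer to 0, under median-of-ratios scaling (132 against 71, median -0.1), scaling by summed gene reads (127 against 90, -0.06), voom on recovered reads (134 against 105, -0.06), removal of the length and level trend (123 against 106, -0.03) and quantile normalization (121 against 98, -0.01). These 295 genes summed to 237937 ± 13710 FPKM in WT and 213621 ± 2628 in GARR2KO (SD, n = 3). The sum over all genes was also lower in GARR2KO, at 621682 ± 3663 FPKM against 657556 ± 21652, and the class held 34.1 to 34.6% of it in the GARR2KO libraries and 35.1 to 36.9% in the WT libraries. For the class sum, the WT libraries lay between 222623 and 249070 and the GARR2KO libraries between 210878 and 216116, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. Among genes at 1 to 4 FPKM, 992 rose and 901 fell, a balance that depended on the scaling: 936 rose and 978 fell after quantile normalization, 956 and 995 with the length and level trend removed, 1017 and 876 with median-of-ratios scaling, 1134 and 792 with scaling by summed gene reads and 1327 and 865 with voom.

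The genes changed 2-fold or more were unevenly spread along the identifier numbers. The densest window of 100 tested genes held 23 of them, where shuffled placements had a median of 12 and at most 18 in 10000 shuffles (p = 0.0001, the smallest the shuffles can give, permutation test). In 4 runs of identifiers, 107 of 599 tested genes (17.9%) had changed 2-fold or more, against 3.6% of the 20932 tested genes outside. The runs were picked for the density of such genes, so this contrast is not itself a test. The first run, numbers 8874 to 9566, held 18 genes that rose and 21 that fell. The second, 19399 to 19957, held 23 and 14. The third, 20340 to 20588, held 5 and 10, and the fourth, 44677 to 44899, held 4 and 12. Zm00001d019414 lies in the second run. Of the 92 genes listed in a single genotype, 17 lay in the runs (18.5%), against 92 of 793 other genes changed 2-fold or more (11.6%) and 577 of 21287 other expressed genes (2.7%). Changes under 2-fold made up 41.2% of tested genes in the runs and 40.2% outside. The runs held 12.4% of the genes changed 2-fold or more, and 757 such genes lay outside them. The edges of the runs follow from the cutoff. Next to the first run, bins of about 100 tested genes held 4 rises and 6 falls (8334 to 8594) and 4 and 4 (8596 to 8843). After it they held 2 and 4 (9666 to 9926), 7 and 4 (9927 to 10198) and 7 and 4 (10199 to 10448). The bin that reaches from after the second run into the third (20087 to 20364) held 6 and 5, so these runs may not be separate. Dense bins also lay away from the runs, with 5 and 7 (4270 to 4621) and 4 and 8 (48491 to 48685). Over all tested genes 4.0% changed 2-fold or more.

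**Figure D3:**
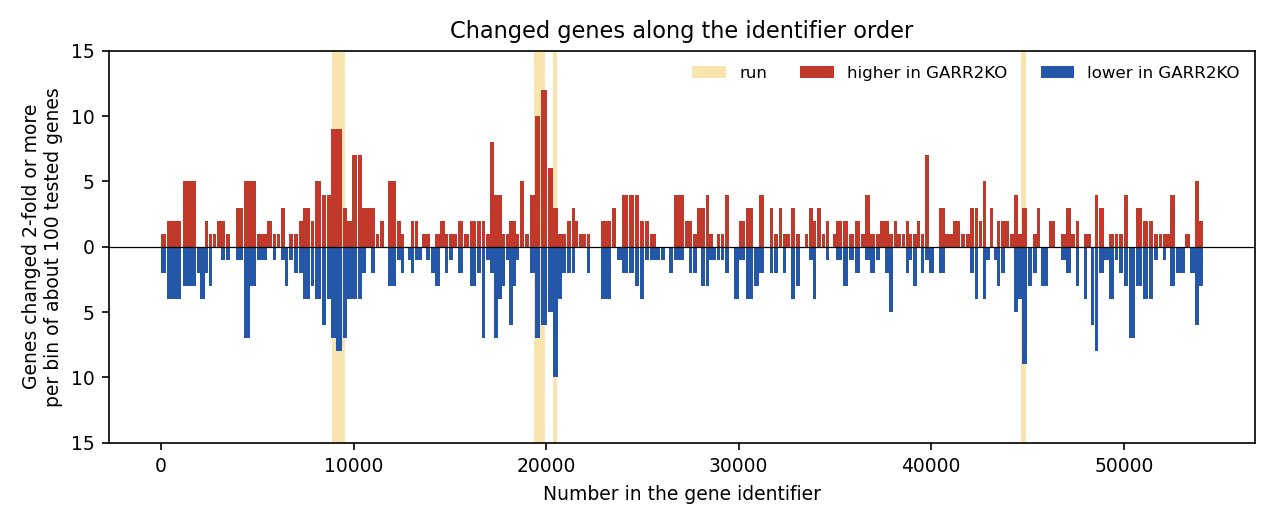
Number of genes changed 2-fold or more per bin of about 100 tested genes, along the number in the gene identifier, with rises in GARR2KO drawn upward in red and falls downward in blue. Shaded bands are the 4 runs; the second, at 19399 to 19957, held 23 rises and 14 falls.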

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

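The alternatives on voom, summed gene reads, the length and level trend and the runs were chosen after the data had been seen. The count of 9517 changed genes lay between 7318 (minimum mean of 5 FPKM, fewer genes tested) and 10612 (voom on recovered reads) under every other setting but a 2-fold minimum, which by construction left 864. Leaving out each library in turn gave 7943 to 8847 changed genes and 855 to 900 changed 2-fold or more. The 864 genes changed 2-fold or more became 1330 with a pseudocount of 0.1, which compresses low values less, 1377 with voom (several choices differ and the cause was not tested) and 521 with a minimum of 5 FPKM, where fewer genes were tested. All 864 were called in the same direction under median-of-ratios scaling, quantile normalization, voom and removal of the length and level trend, as were the 863 tested under scaling by summed gene reads and the 521 tested with a minimum of 5 FPKM. Of the 864, 863 were kept with a pseudocount of 0.1, with the replicate block and with robust moderation, and 857 with no filter. Leaving out a library kept 847 of 853 tested (without WT replicate 3) to 851 of 855. The excess of falls over rises did not hold under every scaling: 4322 rose and 5195 fell on the deposited values, 4938 and 4865 after quantile normalization, 4955 and 4931 with the length and level trend removed, 5348 and 4498 with scaling by summed gene reads and 5866 and 4746 with voom. Leaving out the 4 runs of identifiers left 9163 changed genes, 757 of them 2-fold or more. The 92 genes listed in a single genotype became 130 with a minimum of 0.5 FPKM and 98 to 106 when a library was left out. Both settings loosen the rule, so the count could not fall, and no stricter setting was run. The 4 named genes kept their direction and their call under the alternatives that refit them; leaving out the runs removes Zm00001d019414. The replicate numbers were not treated as pairs, since deviations of same-numbered libraries correlated at -0.051, -0.046 and 0.049, and a fit with the replicate number as a block gave 8963 changed genes. Tests on counts deposited as such did not apply, and the scan along chromosome coordinates was not run. Depth limits what a value of 0 can show, as 1 read in a gene of 2 kb was worth 0.024 to 0.0283 FPKM. In simulations at this depth with 200 changed genes, limma-trend recovered 70% of 1.5-fold and 26.5% of 1.25-fold changes and voom 84% and 52%. The adjusted threshold is stricter there than with 9517 calls, so these shares do not give the recovery in the data.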

Other observations

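The tests of random placement along the identifiers, of genes listed in a single genotype and of scaling by summed gene reads were chosen after the results they bear on had been seen. The other tests were chosen before their results were known.

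The runs of genes changed 2-fold or more were weighed against technical and biological explanations. Random placement was argued against by the permutation test (p = 0.0001, the smallest the shuffles can give). That test was chosen after the pattern had been seen, and it shuffles genes as if they were independent. Noise of low values does not account for the whole pattern, since genes of at least 5 FPKM alone gave a densest window of 24 against a shuffled maximum of 17 (p = 0.0001, permutation test). Close neighbours changing together, within 5 tested genes, were argued against as the whole reason, but less clearly. Keeping 1 changed gene of any within 5 tested genes left a window of 11 (p = 0.0102, permutation test). The shuffled 95th percentile was 10 and the shuffled maximum 12. Which genes belong to a family is not known here, and family members spread more widely are not covered, so gene families stay open. Both scans take the densest window alone and do not give its place. Low values and neighbours changing together therefore stay open for each single run. A change in 1 direction over all runs is argued against by 46.7% of the genes rising (exact interval 37.0 to 56.6%, which treats neighbouring genes as independent). The third run, with 5 up and 10 down, and the fourth, with 4 up and 12 down, leave it open there. Segments from different parents in these places stay open as an explanation. Genes listed in a single genotype, which were not used to find the runs, lay in them at an odds ratio of 1.73 against other genes changed 2-fold or more (exact interval 0.91 to 3.11, one-sided Fisher exact p = 0.0466), which does not decide it. The interval is two-sided while the p is one-sided, and both treat neighbouring genes as independent. The runs are dense in those other genes by selection, and an excess over all expressed genes would be expected under any reason for the runs. That neighbouring numbers are neighbouring genes was not tested, an effect of the knockout on these regions stays open, and most of the genes changed 2-fold or more, 757 of 864, lay outside the runs. Some of these lay in dense stretches beside the run edges, which follow from the cutoff, and some in dense bins away from the runs.

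The many changes under 1.5-fold were weighed next. A trend of the fold change with gene length and level took 0.5% of its variance, and removing it left 92.8% of these 6767 calls in place and in the same direction. Scaling of the libraries was argued against as the reason for most of them, with 89.7% kept under scaling by summed gene reads, 92.9% under quantile normalization and 97.6% under median-of-ratios scaling, although it changed which direction was more frequent. Fewer were kept with the replicate block (87.2%), with no filter (86.8%) and when a library was left out (74.2 to 81.9%, lowest without GARR2KO replicate 2). A growth, harvest or library batch shared by the libraries of each genotype cannot be told apart from the genotype, since the labels name 0 batches that cross them. The loss of GARR2 and a difference in genetic background between the lines stay open as well.

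The real split of the 6 libraries gave 9517 changed genes (limma-trend) and the highest of the other splits gave 0. At an unadjusted p under 0.05 there were 11261 genes and at most 416, and with voom 10612 and 0 changed genes. Each of the other splits puts both genotypes on each side, so the genotype difference widens their spread and their counts are not a chance level. The real split was 1 of 10, and with 10 splits no share can fall under 0.1.

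The reads recovered over the listed genes came to 97.0 to 100.5% of the total that each WT library had been scaled by, and to 94.8 to 96.2% in GARR2KO. In one library, WT replicate 3, they exceeded that total, and the reason was not tested. The 10 most abundant genes took 7.9 to 8.5% of the summed FPKM in WT and 6.8 to 6.9% in GARR2KO.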
